A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

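Yeast cells were grown in rich medium with 2% glucose at 28 °C to an optical density at 600 nm of 0.7 to 1.0 and crosslinked with 1% formaldehyde, per the labels' protocols. Chromatin of an untagged strain and of a strain with FLAG-tagged Acs2 was sequenced as input, with no antibody, and after immunoprecipitation with the M2 antibody against FLAG, 1 library each. The groups were taken from the genotype, antibody and title labels. The processing notes of the submitters name Trimmomatic, BWA, Picard and MACS2 and the genome build R64, without saying which settings were used; duplicate handling, caller settings and read totals are not given in the sources used here.

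The deposited files are 2 peak lists in narrowPeak format, 1 for each immunoprecipitate. Per the file headers, each list sets an immunoprecipitate beside the input of its own strain; the headers do not state which served as background, and the lists were taken as immunoprecipitate over input. Peaks were therefore called per library and not on pooled libraries. Each peak has the authors' fold enrichment, a ratio of the fragments at the summit to the local background. It also has the authors' −log10 p and −log10 q of the summit, and a deposited score that equals 10 times the −log10 q rounded down and was not used further. Fold values were used to describe and rank peaks within a list; where folds of both lists stand side by side they compare the libraries and not the strains.

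Chromosome accessions were translated to chromosome numbers, and the translation was checked on tRNA genes: at least 70% of the tRNA genes of each of the 16 nuclear chromosomes met a peak under its own name, against at most 30.8% under any other. Genes, coordinates and RNA classes came from a RefSeq table of 6477 genes of the R64 assembly. Strand was read from the systematic gene name. The table holds no transposon, centromere, origin or intron features, so 4 of the 12 planned feature classes were not run. Chromosome lengths were taken as the last annotated base or peak base, which makes the chromosome ends approximate. No genome sequence was used, and the planned motif tests were not run. Of 641 list members, 1 (ARG5,6) was not matched.

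MACS2 computes the fold as (n + 1)/(background + 1) and the p from a Poisson tail, and these relations were solved for the fragment count n and the background at every summit. The count came out whole within 0.05 for 30 of 34 untagged and 907 of 912 Acs2-FLAG peaks. The lowest background was taken as the library's depth, 198.4 and 291.1 fragments per base. Exact Poisson intervals of n at 95% confidence were scaled to the fold; they hold the background fixed, cover counting error only, and say nothing about the spread between cultures.

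Peaks sharing at least 1 bp were called shared, with bedtools 2.31.1 as a check. The 890 Acs2-FLAG peaks sharing no base with an untagged peak were the main set. Summits were assigned to the first class holding them, in the order ribosomal RNA, tRNA, small nucleolar RNA, other non-coding RNA, gene body, promoter (500 bp upstream), downstream (300 bp) and other intergenic, with exact Clopper-Pearson intervals. Overlap with 8 feature classes and 18 gene lists was compared with 10000 circular shifts of the list along each chromosome. The one-sided permutation p in each direction was doubled to a two-sided p, with 2e-04 as the smallest value, and adjusted by Benjamini-Hochberg within each family at 0.05. A gene had a peak when the peak met the region from 500 bp upstream to the annotated end. The median fold of each list with at least 5 peaks was placed among 10000 random sets of as many peaks. The ribosomal DNA was taken as chromosome XII 450000 to 500000. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

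The tests were tested on simulated data. Each simulated list had 890 peaks and was tested with 1000 shifts. With 50 peaks planted at ribosomal protein genes, that gene list was called in 100% of 20 simulations. Over these and 20 simulated lists with nothing planted, 0 of 700 tests of unchanged gene lists passed. All peaks not planted were placed at random along their chromosomes, which is close to the chance model of the test. Few such calls thus follow by construction, and peaks that gather at genes for other reasons were not simulated. The fragment count was recovered exactly at 100% of 300 simulated summits. These were made with the same relations, so this checks the solving step only. Random sets of 15 peaks fell outside the central 95% of random medians in 5% of 1000 draws. This follows by construction, since both were drawn from the same peaks.

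Tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The named genes are those at the 15 strongest unshared peaks, the 4 strongest members of each list that passed and up to 2 of each other list, the 6 SESAME genes, and those at the 5 strongest untagged and 5 strongest shared peaks. The remaining shared loci, the RNA genes beyond the 15, the tRNA genes without a peak, RNA170, HHO1, the genes that hold a list member's summit, the genes next to strong peaks outside genes, and the peak between SPL2 and ARO9 were named after their values were seen. The alternatives changed the peak threshold, the removal of shared peaks, merging, repetitive loci, class order, promoter length, gene region, overlap rule and chance model. Leaving out peaks at tRNA and 5S genes, SCR1, RPR1, SNR6 and SNR52, and counting peaks at the depth of the untagged library, were added after seeing the data.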

Results

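Chromatin immunoprecipitation with an antibody against the FLAG tag was sequenced from budding yeast growing in rich medium with 2% glucose. A strain carrying FLAG-tagged Acs2, the nuclear and cytosolic acetyl-CoA synthetase, was set beside an untagged strain. The 4 libraries form 4 groups of 1 library each, an input and an immunoprecipitate per strain, so that no value below has a replicate error and no test between strains was possible. Each immunoprecipitate came with a list of peaks. The untagged list held 34 peaks and the Acs2-FLAG list 912. The background recovered at the summits was 198.4 fragments per base in the untagged library and 291.1 in the Acs2-FLAG library, a ratio of 1.47. At this background, the fold that reaches the lowest −log10 p of the list was 1.26 in the untagged library (lowest −log10 p 3.85) and 1.16 in the Acs2-FLAG library (2.54); at a higher local background, smaller folds were called. Coordinates are on the R64 build, fold enrichments are the authors' own values at the peak summit, and the 95% intervals given with them cover the counting error of the immunoprecipitate only.

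The untagged list measured which loci the antibody and beads recovered without a tagged protein. Outside the ribosomal DNA, it had 20 nuclear peaks, and 19 of them overlapped a peak in the Acs2-FLAG list. Their genes included TDH3, FBA1, PGK1, ENO2 and CDC19, which encode glycolytic enzymes, ADH1 and PDC1 of ethanol fermentation, the cell wall protein gene CCW12, the plasma membrane proton pump gene PMA1, and TEF1 and TEF2, which encode translation elongation factor EF-1 alpha. At TDH3 (chromosome VII, 882812 to 883810) the fold enrichment at the summit was 5.97 (5.71 to 6.24) in the Acs2-FLAG list and 1.91 (1.73 to 2.11) in the untagged list. At ADH1 the values were 5.02 (4.78 to 5.27) and 1.62 (1.45 to 1.80), at FBA1 4.68 and 1.61, at CCW12 4.61 and 1.73, and at CDC19 4.02 and 1.39. Of the 24 untagged nuclear peaks, 23 shared at least 1 bp with an Acs2-FLAG peak. The exception, on chromosome VIII from 375427 to 375700, lay between SPL2 and ARO9 and had a fold of 1.80 (1.62 to 2.00).

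**Figure D1:**
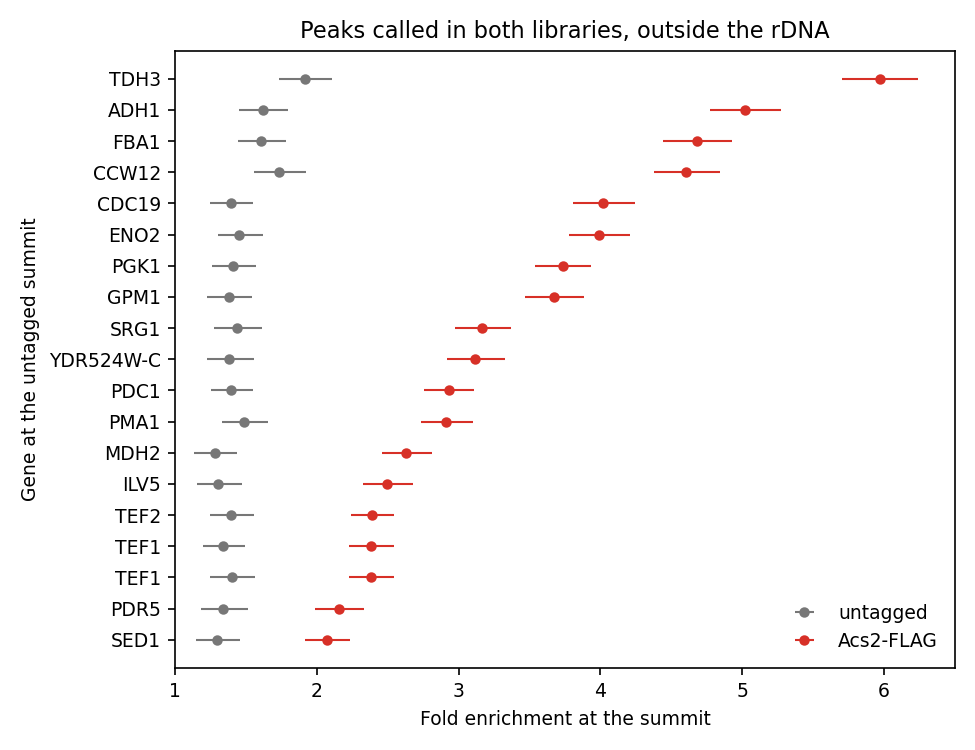
Fold enrichment at the summit (horizontal axis, no unit) of the 19 untagged peaks outside the ribosomal DNA that overlapped an Acs2-FLAG peak, named by the gene at the untagged summit; TEF1 appears for each of its untagged peaks. Points are single libraries and bars are 95% counting intervals; the Acs2-FLAG values run from 2.07 at SED1 to 5.97 at TDH3.

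Outside the ribosomal DNA, the fold was higher in the Acs2-FLAG library at 19 of the 19 overlaps, and the counting intervals lay apart at all 19. The ratio of the folds had a median of 2.21 and ran from 1.60 to 3.12. The part of the fold above 1 was a median of 4.98 times as large (3.40 to 7.76), a ratio that rests on small untagged values such as 1.29 (1.15 to 1.45) at SED1. This compares those libraries, each against its own background, and not the strains. In the ribosomal DNA the order was the other way round at 3 of 4 overlaps. The fold was 2.37 (2.34 to 2.39) in the Acs2-FLAG library and 3.34 (3.31 to 3.38) in the untagged library at ETS1-1, 2.39 and 3.43 at ETS1-2, and 2.79 and 4.57 next to RRT15. At RDN5-2 it was 1.31 and 1.03. The mitochondrial genome had 10 untagged peaks, the strongest at 21S_RRNA with folds of 2.82 (2.71 to 2.94) and 2.44, and 0 Acs2-FLAG peaks.

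From the Acs2-FLAG side, 22 of 912 peaks (2.41%, exact Clopper-Pearson interval 1.52 to 3.63) shared a base with an untagged peak. Circular shifts of the list gave a mean of 4.25 such peaks and a maximum of 14 in 10000 shifts (two-sided permutation p = 2e-04, the smallest these shifts can give). The 22 shared peaks had a median fold of 2.92 and the 890 others a median of 1.60. The accounts that follow use the 890 peaks without an untagged counterpart unless stated otherwise. Lack of an untagged peak does not clear a weak peak of background. At the lowest untagged background, a fold under 1.26 would not reach the lowest −log10 p of that list. Outside the ribosomal DNA, no shared Acs2-FLAG peak had a fold below 2.07 (SED1), where the untagged fold was 1.29. Background at weaker Acs2-FLAG peaks may thus have gone uncalled.

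The strongest unshared group was the genes transcribed by RNA polymerase III. An Acs2-FLAG peak covered 270 of the 275 nuclear tRNA genes (98.2%, exact interval 95.8 to 99.4). An untagged peak covered 0 of 275 (upper exact bound 1.33%). Exact intervals of gene shares treat the genes as independent. They do not cover the calling threshold or a repeat of the library, so the bound does not limit weak untagged signal at these genes. The 264 peaks at tRNA genes had a median fold of 3.18, with quartiles of 2.89 and 3.51, and a median width of 510 bp. Their summits lay a median of 11 bp from the midpoint of the tRNA gene. The tRNA genes without a peak were SUP53, YNCC0008W, YNCC0009C, YNCL0009C and YNCN0008C.

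Among all 912 Acs2-FLAG peaks, shared ones included, 282 had a fold above 2.5; 247 of these overlapped a tRNA gene, and so did 88 of the 100 strongest. Among the 15 strongest unshared peaks, 13 lay at tRNA genes, led by YNCF0009C at 4.56 (4.33 to 4.79), YNCL0033C at 4.50, YNCG0028W at 4.49, YNCB0004W at 4.43 and YNCD0024C at 4.43. The rest of the 13 were YNCK0010W at 4.33, SUP61 at 4.27, YNCG0042C at 4.27, SUF11 at 4.22, YNCO0008W at 4.19, SUF8 at 4.18, SUP54 at 4.15 and YNCE0009C at 4.15. The strongest of all unshared peaks was at SCR1 (chromosome V, 441987 to 442508), the RNA of the signal recognition particle, with a fold of 4.67 (4.46 to 4.89). The remaining member was the glycolytic gene TPI1 (chromosome IV, 555726 to 556472) at 4.13 (3.92 to 4.35).

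The other single-copy genes of this polymerase on the list examined, SNR52, SNR6 and RPR1, had peaks too. SNR52, a small nucleolar RNA, had a fold of 3.89 (3.67 to 4.12), SNR6, the U6 spliceosomal RNA, 2.93 (2.75 to 3.12), and RPR1, the RNA of RNase P, 2.33 (2.17 to 2.50). None of these genes or SCR1 had an untagged peak. RNA170, a further small non-coding RNA gene, had no Acs2-FLAG peak, and ZOD1, another, had an unshared peak of 1.59 (1.45 to 1.74). Among the 5S ribosomal RNA genes, 5 of 6 had an Acs2-FLAG peak, and 1 of 6 had an untagged peak. RDN5-4, RDN5-5 and RDN5-6 had unshared peaks with folds of 2.45, 2.32 and 2.26. RDN5-1 lay in the shared peak at ETS1-2, with the summit 7177 bp away, the peak at RDN5-2 was also shared, and RDN5-3 had none. The 5S genes and many tRNA genes have near-identical copies, so a value at a single copy is uncertain.

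**Figure D2:**
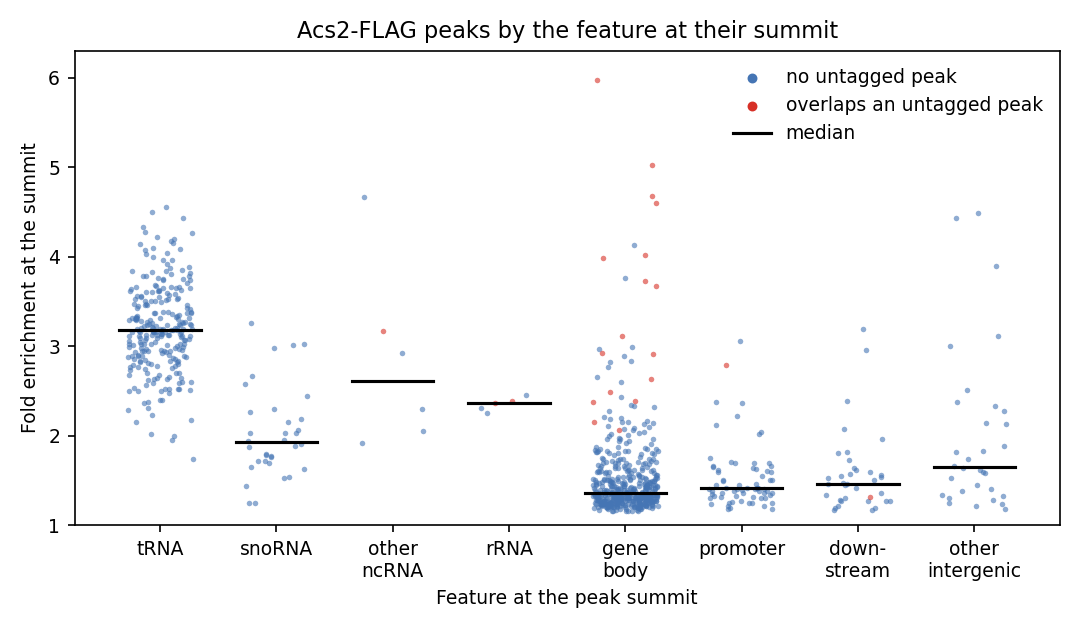
Fold enrichment at the summit (vertical axis, no unit) of the 912 Acs2-FLAG peaks, placed by the annotated feature at the summit. Each point is a peak, red points overlap an untagged peak, and the lines are class medians; tRNA summits have a median of 3.18 and summits in protein-coding gene bodies 1.36.

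By the feature at the summit, 456 of the 890 peaks lay in a protein-coding gene body (51.2%, exact interval 47.9 to 54.6) and 257 in a tRNA gene (28.9%, 25.9 to 32.0). Promoters, taken as 500 bp upstream of the annotated start, held 7.64% of the summits after RNA genes and gene bodies were assigned first. Counted without this order, 238 summits (26.7%) lay in a promoter, many of them also in another class. Downstream regions held 3.93%, small nucleolar RNA genes 3.82%, other intergenic sequence 3.60%, other non-coding RNA genes 0.562% and ribosomal RNA genes 0.337%. The median fold was 3.18 at tRNA summits, 1.93 at small nucleolar RNA summits, 1.41 in promoters and 1.36 in gene bodies. Of the 24 untagged nuclear summits, 17 lay in a gene body and 0 in a tRNA gene.

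Compared with shifted copies of the list, the peaks met tRNA genes and small nucleolar RNA genes far more often. A tRNA gene was met by 264 peaks against a mean of 18.7 after shifting, which is 14.1 times as many, and a small nucleolar RNA gene by 55 against 5.18, or 10.6 times. With the summit counted in place of any base, the ratios were 153 and 32.4, and among the 445 strongest peaks they were 26.0 and 15.2. Downstream regions were met by 534 peaks against 354.2 (1.51 times) and promoters by 547 against 415.7 (1.32 times). The adjusted permutation p was 3.2e-04 for each of these 4 classes. Other non-coding RNA genes were met by 9 peaks against 3.24 (adjusted permutation p = 0.0094). Fewer peaks than after shifting met gene bodies, 660 against 816.7 (adjusted permutation p = 3.2e-04), and the terminal 20 kb of the chromosomes, 21 against 47.9 (adjusted permutation p = 5.3e-04). Ribosomal RNA genes did not pass, with 3 peaks against 1.75 (adjusted permutation p = 0.54). Among the 445 strongest peaks, the same 3 peaks stood against 0.822 and passed (3.65 times, adjusted permutation p = 0.0488). All 3 lay in the ribosomal DNA; with no peak removed, 6 peaks met these genes (3.07 times, adjusted permutation p = 0.0506).

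Without the peaks at RNA polymerase III genes, 3 calls no longer passed: the ratio to shifted peaks was 0.613 for the chromosome ends, 0.976 for gene bodies and 2.60 for other non-coding RNA genes. The tests describe this list of peaks, since 1 library stands for each strain. In the untagged list, 0 of 8 classes passed the same test over 24 nuclear peaks. With so few peaks the test could miss an excess, so this does not show that the background lacks these patterns. Downstream regions were at 1.40 times there (14 peaks against 10.0), promoters at 0.949 times, and tRNA genes had 0 peaks against 0.673.

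Cytosolic ribosomal protein genes formed the largest protein-coding group with peaks: 99 of 138 had an unshared Acs2-FLAG peak in the region from 500 bp upstream to the annotated end, against a mean of 20.3 after shifting (4.87 times, adjusted permutation p = 0.0012). Their strongest peaks were at RPL36A with 3.26 (3.06 to 3.47), RPL9B with 3.19, RPL33B with 3.03 and RPL26A with 2.99. The summits of the RPL36A and RPL33B peaks were nearest to the small nucleolar RNA genes SNR11 and SNR17A, and that of the RPL26A peak to the tRNA gene TRR4. Of the histone genes, 9 of 10 had such a peak (8.21 times, adjusted permutation p = 0.0012). A single peak spanned HHT2 and HHF2, for H3 and H4, with a fold of 2.28 (2.12 to 2.44), HTB2 and HTA2, for H2B and H2A, had 2.08 and 2.07, and the linker histone gene HHO1 had none.

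Cell wall protein genes had peaks at 15 of 21 (4.12 times, adjusted permutation p = 0.0012), among them HSP150 and CIS3, which share a peak of 2.15 (2.00 to 2.31). The strongest at this list, 4.27 at CRH1, has its summit at the tRNA gene YNCG0042C, and the PIR1 peak of 2.16 has its summit at YNCK0005C. Genes of glycolysis and fermentation had unshared peaks at 11 of 22 (2.59 times, adjusted permutation p = 0.0076), and 19 of 22 had any Acs2-FLAG peak, since 8 lie at untagged peaks. The strongest unshared members were TPI1 with 4.13, TDH2 with 3.76 (3.56 to 3.98), ENO1 with 2.97 and GLK1 with 2.83. This was also the list that passed in the untagged library, with 8 of 22 genes against 0.166 after shifting (adjusted permutation p = 0.0036). Cell wall genes, with 2 of 21 against 0.139, did not pass there (adjusted permutation p = 0.092). Translation factor genes, with 2 of 28 against 0.144, did not pass either (adjusted permutation p = 0.102). Over 24 untagged nuclear peaks, a list that did not pass is not shown to be free of background.

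**Figure D3:**
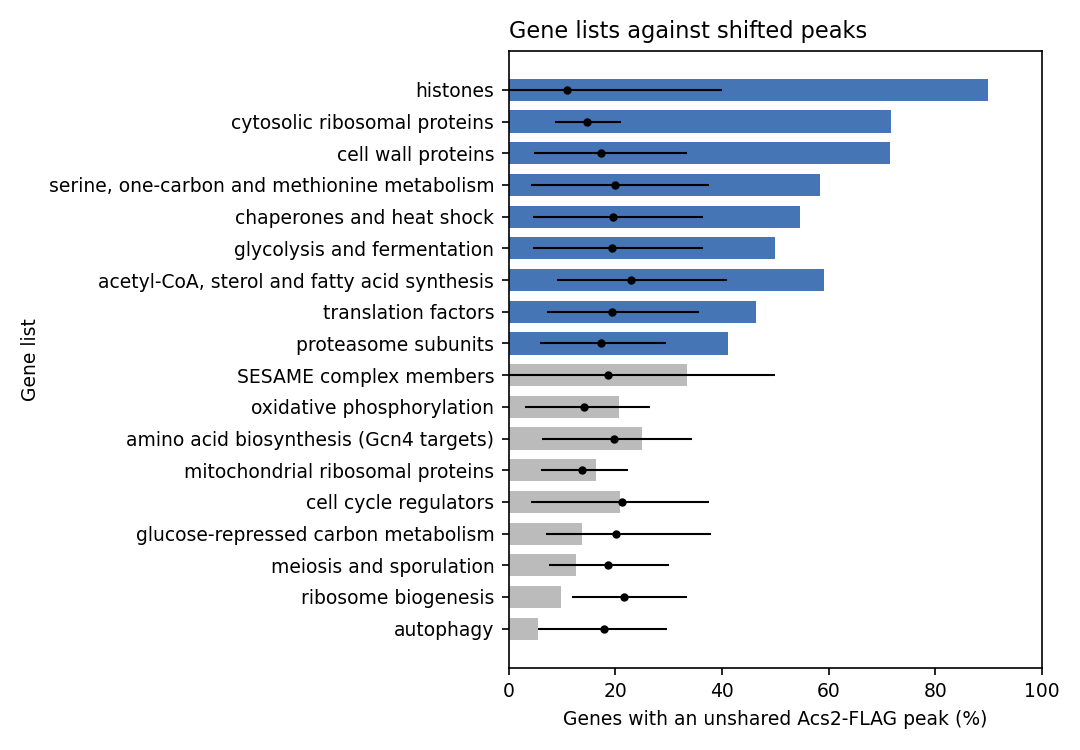
Share of each gene list (percent, horizontal axis) with an Acs2-FLAG peak not shared with the untagged list. Bars are observed shares, blue where the adjusted p passed 0.05; points and lines are the mean and central 95% of 10000 shifted lists. Histone genes reach 90.0% and autophagy genes 5.41%.

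Of the genes of acetyl-CoA, sterol and fatty acid synthesis, 13 of 22 had an unshared peak (2.58 times, adjusted permutation p = 0.0014). The strongest were PDA1 with 2.19 (2.03 to 2.36), in a peak with its summit at BMH1, FAS2 with 1.81 (1.65 to 1.97), ALD6 with 1.70 and FAS1 with 1.51. PDA1 encodes a subunit of pyruvate dehydrogenase, FAS1 and FAS2 fatty acid synthase, and ALD6 the cytosolic acetaldehyde dehydrogenase. The list of serine, C1 and methionine metabolism had 14 of 24 (2.92 times, adjusted permutation p = 0.0014), with MET17 at 3.32 from a peak with its summit at the tRNA gene YNCL0037W, the serine hydroxymethyltransferase gene SHM2 at 2.77 (2.59 to 2.96), GCV1 at 1.74 and SER2 at 1.72 in a peak with its summit at TRX2.

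Chaperone and heat shock genes had 12 of 22 (2.80 times, adjusted permutation p = 0.0018), with SSA1 at 3.11 in a peak with its summit at the tRNA gene TRN1, SSA2 at 2.20 (2.07 to 2.34), HSP104 at 1.60 and HSP60 at 1.58. Translation factor genes had 13 of 28 (2.40 times, adjusted permutation p = 0.0036), with HYP2 at 3.63 and TIF4631 at 2.53, both in peaks with summits at tRNA genes, RPG1 at 1.82 in a peak with its summit at ECM33, and EFB1 at 1.71. Proteasome genes had 14 of 34 (2.39 times, adjusted permutation p = 0.0049), with PRE1 at 3.05 and RPT2 at 2.98, again with summits at tRNA genes, RPN12 at 1.64 and PRE5 at 1.41. The summits of the RPN12 and PRE5 peaks were at HXK1 and YMR315W.

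These 9 lists passed with more genes than after shifting and 0 of the 18 lists with fewer. At each of the 9, the median fold of the unshared peaks was at most 1.97 (glycolysis). This lies below 2.07, the lowest shared Acs2-FLAG fold outside the ribosomal DNA, so background at many of these genes may have gone uncalled. With the peaks at RNA polymerase III genes left out, the same 9 lists passed. In promoters alone, 5 of them no longer passed. The ratio was 2.75 for the chaperone list, about as high as before but from 6 genes (adjusted permutation p = 0.12), 1.99 for serine, 1.79 for acetyl-CoA, 1.76 for translation factors and 1.16 for the proteasome. Among the 445 strongest peaks these lists were at 0.899, 1.47, 1.07, 1.36 and 0.936 in the same order, and the cell wall list, at 3.01 times from 6 genes, did not pass either (adjusted permutation p = 0.11). The proteasome list did not pass among peaks with a −log10 q of at least 5 (1.58 times, adjusted permutation p = 0.41). Among the lists that still passed, the glycolysis ratio was 4.91 in promoters alone and 4.25 with no peak removed, and among the 445 strongest peaks the histone ratio was 14.8 and the ribosomal protein ratio 3.07.

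Acs2 belongs with Cdc19, Ser33, Shm2, Sam1 and Sam2 to the complex SESAME, which joins pyruvate kinase to serine and S-adenosylmethionine enzymes. Of these 6 genes, CDC19 (chromosome I, 71786 to 73288) had the shared peak of 4.02 and SHM2 (chromosome XII, 257992 to 259401) the unshared peak of 2.77. SAM1 (chromosome XII, 515262 to 516410) had a peak of 1.28 (1.16 to 1.41). ACS2, SER33 and SAM2 had no peak. The list with 2 of 6 genes at unshared peaks did not pass (1.79 times, adjusted permutation p = 0.68).

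The other lists did not pass either, and many of their strongest members shared a peak with a neighbouring tRNA gene that held the summit. Mitochondrial ribosomal protein genes had peaks at 11 of 67 (adjusted permutation p = 0.68), with RSM26 at 3.74 and MRPS8 at 3.66, both with tRNA summits. Ribosome biogenesis genes had 5 of 51 (0.455 times, adjusted permutation p = 0.083), with UTP22 at 3.37 and NOC4 at 2.96, also with tRNA summits, and autophagy genes 2 of 37 (0.303 times, adjusted permutation p = 0.088), ATG31 at 3.74 with a tRNA summit and ATG19 at 1.40. Ribosome biogenesis genes passed with fewer genes when the gene body alone or the summit was counted, and autophagy genes did so in Fisher's exact test.

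Amino acid biosynthesis genes under Gcn4 had 8 of 32 (adjusted permutation p = 0.68), with TRP3 at 1.70 in a peak with its summit at SNR64 and HIS1 at 1.48. Oxidative phosphorylation genes had 7 of 34 (adjusted permutation p = 0.59), with ATP1 at 3.05 and QCR6 at 1.70 in a peak with its summit at PHO4. Glucose-repressed genes had 4 of 29 (adjusted permutation p = 0.68), with FBP1 at 3.70 and POX1 at 3.28, meiosis and sporulation genes 5 of 40 (adjusted permutation p = 0.62), with NDT80 at 3.51 and SPO13 at 3.34, and cell cycle regulators 5 of 24 (adjusted permutation p = 1), with CLB6 at 3.47 and CLB5 at 3.16. The summits of the ATP1, FBP1, POX1, NDT80, SPO13, CLB6 and CLB5 peaks lay at tRNA genes. Meiosis genes passed with fewer genes when the summit was counted. Across all 6002 protein-coding genes, 1188 had an unshared peak, against a mean of 1124.5 after shifting.

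**Figure D4:**
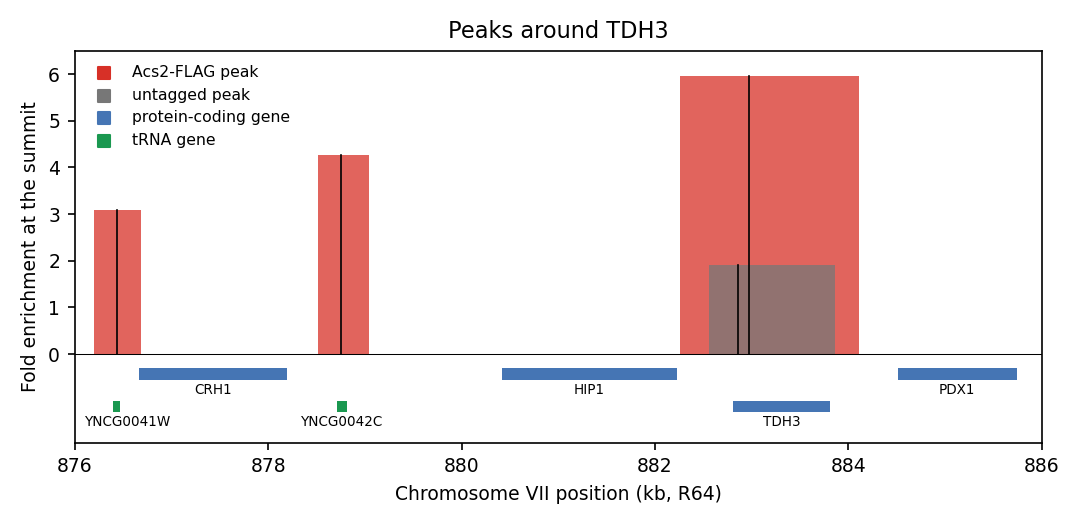
Peaks on chromosome VII around TDH3 (position in kb, horizontal axis); the height of a box is the fold enrichment at the summit (vertical axis, no unit), its width the extent of the peak, and the black line the summit. TDH3 has a peak in both lists (5.97 and 1.91), while the tRNA genes YNCG0041W (3.09) and YNCG0042C (4.27) have an Acs2-FLAG peak and no untagged peak.

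Within the list, the peaks at ribosomal protein genes were many, with folds below those of most random sets. The median fold of the 107 peaks at these genes was 1.40, at percentile 0.07 among 10000 random sets of as many unshared peaks. Peaks at acetyl-CoA, sterol and fatty acid genes had a median of 1.30 (18 peaks, percentile 0.15) and those at proteasome genes 1.30 (15 peaks, percentile 0.615). No list lay above the central 95% of the random medians. Once the peaks at RNA polymerase III genes were left out, the glycolysis list with a median of 1.97 lay at percentile 100 and the histone list with a median of 1.92 at percentile 99.7, both above that range. The ribosomal protein list, with a median of 1.40 against 1.40 for all 619 peaks then left, moved to percentile 61.8. The acetyl-CoA list, with its median still at 1.30, lay just inside the range at percentile 2.68, and the proteasome list stayed below it at percentile 1.22.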

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

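The settings without peaks at RNA polymerase III genes and at the depth of the untagged library were chosen after seeing the data; the other settings were planned. Of 436 values computed under an alternative, 382 kept their direction and side of the threshold or stayed within their counting interval or 1.5 times the count. Among tests of gene lists, 200 of 216 kept their side of the threshold, and 67 of 72 tests of feature classes did. Without the ribosomal DNA, mitochondrial genome and chromosome tips, the untagged list held 20 peaks. The share of tRNA summits was 35.2% among peaks with a −log10 q of at least 5 and 57.8% among the 445 strongest. Gene bodies held 44.2% and 22.9% in these settings, and 46.4% with the promoter placed before the gene body. Without peaks at RNA polymerase III genes, tRNA summits made up 0% and the ratio of tRNA genes to shifted peaks turned round to 0, both by construction. There, gene bodies held 73.5% of the summits, 3 feature classes were met more often and 1 less often than by shifted peaks, 2 gene lists had a high median fold and 1 a low one. Gene lists met more often numbered 3 among the 445 strongest peaks and 4 with promoters alone. Gene lists met less often numbered 1 with the gene body alone, 2 with the summit and 1 with Fisher's exact test. With no peak removed, 1 list had a high median fold, and among the 445 strongest peaks 1 had a low one. Where no construction shows it, the cause was not tested. Motif tests and their alternatives were not run. No paired analysis was possible because each group held 1 library. At the lowest background of the untagged library, a fold under 1.26 would not reach the lowest −log10 p of its list, 3.85.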

Other observations

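The tests in this part were chosen after the results they bear on had been seen. Small nucleolar RNA genes, most of them transcribed by RNA polymerase II, were a further group with Acs2-FLAG peaks and no untagged peak. A peak covered 68 of 76 (89.5%, exact interval 80.3 to 95.3), with a median fold of 1.83 over 55 peaks, and an untagged peak covered 0 of 76. This median lay below the lowest shared Acs2-FLAG fold outside the ribosomal DNA, 2.07, so background at many of these genes may have gone uncalled. Of the 68, 34 had the summit inside the gene and 6 lay in a peak that also overlapped a tRNA gene. SNR17A, a U3 RNA gene, had a fold of 3.03 (2.83 to 3.24), SNR37 3.02 and SNR40 2.98. The 6 annotated spliceosomal RNA entries, of which SNR7-L and SNR7-S are forms of the same U5 gene, lay under 5 peaks, among them SNR19, the U1 RNA, with 2.30 (2.13 to 2.48) and LSR1, the U2 RNA, with 1.92.

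Summits inside protein-coding genes lay towards the 3′ end. With each gene divided into 4 equal parts, 13.5% (exact interval 10.5 to 17.0) of 452 such summits outside RNA polymerase III peaks lay in the part next to the start. The middle parts held 24.6% and 29.0%, and the part next to the end 33.0% (28.6 to 37.5). These shares were not compared with shifted peaks. Most of the 17 untagged summits in gene bodies also lay nearer the end than the start of their gene, with exceptions at ILV5 and TEF1. The lean towards the 3′ end is thus not particular to the Acs2-FLAG list. Of the Acs2-FLAG peaks, 43 overlapped no annotated gene, and 6 of these had a fold above 2. The strongest, on chromosome VIII from 562235 to 562605, had a fold of 3.11 (2.99 to 3.24) near YHR219W. It ended at the last base used for that chromosome, and its local background was 792 fragments per base against 291.1 for the library. Others were next to RRT15 (2.79, shared with the untagged list), PUG1 (2.38), YLL066C (2.37), YFL064C (2.28) and PHM8 (2.23). Of the 6, 4 lay in the terminal 20 kb of a chromosome and 1 in the ribosomal DNA, where repeated sequences make the position and fold of a peak uncertain.

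The Acs2-FLAG list held peaks at tRNA genes and the untagged list none. The values argue against lower depth of the untagged library as the cause, since 264 of 264 tRNA gene peaks would still pass its threshold at its depth. A background of both libraries, stronger in the Acs2-FLAG library, cannot be told apart from a signal of the tag. A cut was set at the median fold of the 18 shared peaks outside the ribosomal DNA (3.14). Above it, 0 of 145 tRNA gene peaks were called in the untagged library, against 9 of 13 other peaks. These counts decide nothing, since the cut came from the shared peaks and no tRNA gene peak was shared. The groups also differed in width. All 13 other peaks but only 6 of the 145 were as wide as the narrowest shared peak (1186 bp), and a narrow peak may be harder to call. These are widths in the Acs2-FLAG list, and the untagged list itself held nuclear peaks as narrow as 246 bp. Acs2 binding at these genes stays open as an untested biological explanation, and reads shared between tRNA copies were not tested.

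The Acs2-FLAG list was longer than the untagged list. Greater depth alone is an unlikely cause, since 805 of its 912 peaks would pass at the depth of the untagged library, against 24 untagged nuclear peaks. With 1 library per strain, how much of the fold at shared genes such as TDH3 and ADH1 was background could not be measured. A difference between strains, immunoprecipitations or libraries remains open.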
